A study of Mus musculus with 4 samples.

How the data were processed

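Expression was measured on mouse bead arrays in bone marrow-derived dendritic cells (BMDCs). Per the labels' protocols, marrow from the tibiae and femurs of C57BL/6 mice aged 6 to 8 weeks was cultured for 8 days with recombinant GM-CSF at 20 ng/ml. The cells were then kept for 4 hours in medium alone or with rehydrated Bifidobacterium at 1 cell to 10 bacteria. RNA with an integrity number of 10 was amplified and labelled with biotin, per the labels. Each group held 2 arrays, and all 4 were used. Groups and replicate numbers came from the sample titles, and every column of per-sample values could be assigned to an array. The labels do not say whether the replicates came from separate cultures or mice. The species and strain of Bifidobacterium and the array slides are not given in the sources used here.

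The main input was a probe table that the authors exported with the GenomeStudio gene expression module 1.9.0. Its intensity values are mean bead signals per probe, deposited without background subtraction and without normalisation between arrays, per the file headers. The count values are numbers of beads per probe and array, as deposited, per the file headers (medians 36, 34, 36 and 35, range 7 to 141). The detection p-value of each probe compares its signal with the negative controls of the same array, per the file headers. A second sheet gives 798 negative and 34 other control probes; it has no header and was taken as the same export. Biotin control intensities were 2165.4 and 2285.8 on the unstimulated arrays and 2162.35 and 2206.5 on the stimulated arrays. Mean negative control intensities were 88.9 and 93.1, and 85.7 and 88.3. The highest intensities were 16035.6, 16999, 15050.5 and 15095.9, in the same order. The authors' processed values are linear intensities that share 1 distribution over the arrays and include values below 0 (column medians 4.1, 4.1, 4 and 4). From this they were judged to be background-subtracted and quantile-normalised, and the direction and centring need no assumption since they are intensities per array; the method is not given in the sources used here.

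In R 4.3.3 with limma 3.58.1, intensities were background-corrected by normexp with the negative controls, given an offset of 16, quantile-normalised and put on a log2 scale (neqc). Of 25594 probes, 24103 (94.2%) matched the gene table (GRCm38.p6) by transcript accession and 1491 kept the symbol of the array table, giving 17929 symbols. The 103 probes found only in the authors' processed table were not used here. Probes with a detection p under 0.01 on at least 2 of the 4 arrays were tested (10030 probes), and each of 7557 genes was represented by the probe with the highest mean over all arrays. A linear model with empirical Bayes moderation compared stimulated with unstimulated arrays, two-sided, with 2 residual and 3.83 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A gene not above background on both arrays of a group is given as a lower bound of its fold, or, where only 1 array detected it, with that number. No test of single arrays as outliers is possible with 2 per group.

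The 30 gene lists, the tests of genes and lists, the rule for named genes and most other settings to compare were fixed before the data were examined. Scaling to the median of the tested probes and camera on ranks were added after the data were seen, as were most of the tests of causes. The lists were written from textbook knowledge. Some genes are in more than 1: Irf7 and Bst2 in the plasmacytoid and type I interferon lists, Ccr7 in the maturation and conventional dendritic cell lists, Irf8 in the conventional dendritic cell and interferon-gamma lists, Relb in the NF-kB and maturation lists, Csf1r and Fcgr1 in the macrophage and receptor lists, and Thy1 in the T cell and stromal lists. Lists with at least 5 tested genes (26) were tested with camera at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. List counts use calls adjusted over all genes, and are also given adjusted over the list alone. The rule names the 10 largest increases and decreases, up to 4 called members of each list with the largest changes, called members of lists with 5 or fewer of them, and 21 genes fixed in advance; a few genes that it names are not reported here. Members behind small counts within a list, such as the few that fell where most rose, were named after their values were seen.

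Alternatives to the settings covered background correction, scaling between arrays, the authors' processed values, the filter on dim probes, several probes per gene, the variance model, a 2-fold threshold, a block for the replicate number, leaving out each array (which leaves 1 array in its group and 1 residual degree of freedom), and for lists an estimated inter-gene correlation, ranks and the self-contained test fry. For the authors' values, negative values were set to 0 and the same offset was added before taking log2. The procedure was tested on simulated data built on these arrays. In 5 simulations with 200 changed genes each, drawn from the brighter genes, it recovered 65 of 335 changes of 1.5-fold (19.4%), 279 of 335 of 2-fold (83.3%) and 328 of 330 of 4-fold (99.4%). It made 12 false calls among 43244 unchanged genes (1.75% of its calls) and 0 among 43390 when no gene was changed. Of random lists, 7 of 250 (2.8%) had an unadjusted camera p under 0.05, and 5 of 5 raised lists were found. The simulations raised as many genes as they lowered and drew the noise of each probe independently. They therefore do not test the scaling where most genes change, or camera where genes are correlated. In the data 64.3% of tested genes were called, a far larger share than was changed in the simulations. The Benjamini-Hochberg threshold is stricter where fewer genes change, so the recovery rates for small changes do not carry over to the data. Bead noise was checked with the deposited bead errors: replicate differences had 1.37 times the SD expected from bead noise in the unstimulated group (5157 probes) and 1.33 times in the stimulated group (3821 probes). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.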

Results

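Bone marrow-derived dendritic cells (BMDCs) are antigen-presenting cells grown from marrow precursors with the growth factor GM-CSF. The series asked how their gene expression changes on contact with Bifidobacterium, a genus of commensal gut bacteria. BMDCs of C57BL/6 mice were kept for 4 hours either in medium alone (unstimulated) or with rehydrated Bifidobacterium at 10 bacteria per cell. Expression was read on 4 bead arrays, 2 per group, with 25594 probes for messenger RNA in the table used here. On the unstimulated arrays 9937 and 10091 probes (38.8% and 39.4%) were above background, against 9066 and 8415 (35.4% and 32.9%) on the stimulated arrays. Mean raw intensity was 265 and 311 on the unstimulated arrays and 222 and 233 on the stimulated ones. After normalisation, the replicates correlated across the tested genes with r = 0.996 (unstimulated) and r = 0.994 (stimulated), and arrays of different groups with r = 0.887 to 0.888. Genes are not independent replicates, so these are descriptions of the arrays. Replicate differences had an SD of 0.17 log2 units in the unstimulated group and 0.23 in the stimulated group. With 2 arrays per group the number of arrays limits the precision, and a call lost without 1 array, as given for some genes and lists, rests on 1 residual degree of freedom. These fits kept the filter of 2 arrays, so genes detected only in the group left with 1 array were not tested in them. List medians in such fits can therefore differ because members are missing. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical. Slides are not given either, and a difference between slides that coincided with the groups could not be told apart from stimulation.

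The gene with the largest increase on contact with Bifidobacterium was Cxcl1, a neutrophil chemoattractant. It rose from 5.41 ± 0.26 to 13.67 ± 0.05 log2 units (mean ± SD, n = 2 each), a 307-fold increase (log2 fold change 8.26, SE 0.14). Next in size came the chemokines Cxcl10 (7.54, SE 0.09) and Cxcl2 (7.33, SE 0.09) and the antiviral enzyme Rsad2, also called viperin (7.10, SE 0.16). Il6, the cytokine that drives the acute-phase response, was not above background on either unstimulated array and rose at least 72.8-fold. The other increases among the 10 largest were in the protease inhibitor Serpinb2 (6.45), the co-stimulatory receptor Cd40 (6.38), the interferon-induced Oasl1 (6.33, above background on 1 of 2 unstimulated arrays), the endothelin precursor Edn1 (6.05) and the acute-phase protein Saa3 (5.92). Their adjusted p-values ran from 1.42e-06 for Cxcl10 to 3.81e-06 for Rsad2.

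As measured, the largest decreases were smaller than the largest increases. Several of these decreases are known only as lower bounds, so their true sizes cannot be ranked. The increases have limits too, as that of Il6 is a lower bound. On the stimulated arrays Rsad2, Cxcl1 and Cxcl2 had means of 13.70, 13.67 and 13.43, near the highest mean of a tested gene over all arrays (13.91). Whether such bright values are compressed was not tested. Pald1, which encodes a phosphatase-domain protein, was not above background on either stimulated array and fell at least 8.61-fold. Cdca7, a cell division cycle-associated gene, fell at least 9.59-fold, Tmem53 at least 8.29-fold, the kinase gene Sbk1 at least 7.32-fold, and Ppargc1b, a coactivator of mitochondrial genes, at least 5.37-fold. The cell cycle transcription factor E2f2 fell with a log2 fold change of -3.18 (SE 0.09). The late endosomal GTPase gene Rab7b fell with -3.22 (SE 0.10), and Fam78a with -3.27 (SE 0.10). Daglb, which encodes a lipase that makes an endocannabinoid, fell with -3.53 (SE 0.09), while its dimmer second probe gave -0.35 (adjusted p = 0.0771). Cnr2, an endocannabinoid receptor gene, fell with -3.11 (SE 0.12) and was above background on 1 of 2 stimulated arrays.

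**Figure D1:**
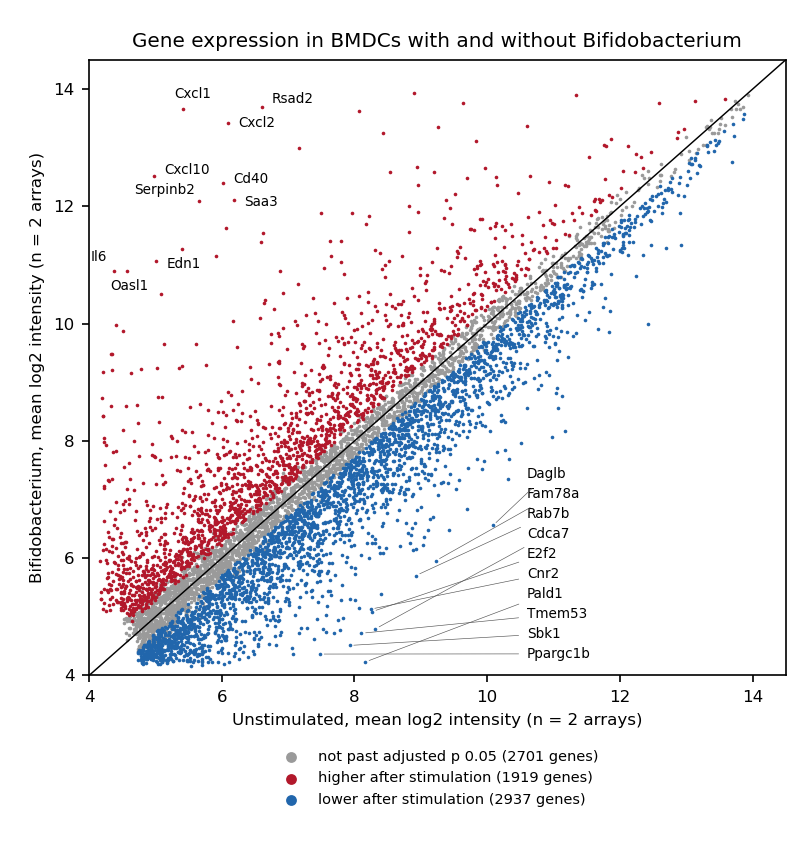
Mean normalised log2 intensity of each of the 7557 tested genes on the 2 unstimulated arrays (horizontal axis) and the 2 Bifidobacterium arrays (vertical axis); the line marks equal values. Red points are the 1919 genes that rose, blue points the 2937 that fell and grey points those not past an adjusted p of 0.05, and labels mark the 10 largest increases, led by Cxcl1 (log2 fold change 8.26), and the 10 largest decreases. The split of red to blue points changes with the scaling between arrays.

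Of 7557 genes tested with limma (two-sided), 4856 (64.3%) passed a Benjamini-Hochberg adjusted p of 0.05, 1919 higher and 2937 lower after stimulation. Changes of at least 2-fold were found in 718 of the higher and 797 of the lower genes. Fewer genes were lower without unstimulated replicate 1 or 2, but only 4336 of the 4856 called genes were tested in each of these fits. Genes detected only on unstimulated arrays could not pass the filter there. Without variance moderation 1160 were higher and 1604 lower. The balance of directions depended on the scaling: 39.5% of changed genes were higher with quantile normalisation, 12.4% (744 higher, 5266 lower) with scaling to the median of all probes, and 57.0% (2709 higher, 2044 lower) with scaling to the median of the tested probes. These scalings moved the median log2 fold change of all tested genes from -0.14 to -0.69 and to 0.10, so changes near these sizes have no settled direction. The median scalings differ only by a constant shift, and that to the tested probes was added after the data were seen. Median raw intensities, unstimulated arrays first (93.3, 98.7, 89 and 91.9), lay close to the mean negative controls (88.9, 93.1, 85.7 and 88.3). The median of all probes is therefore that of a probe near background. Fold sizes of dim genes depended on the background correction: without it, Cxcl1 had a log2 fold change of 6.82, Il6 one of 4.40, and 382 higher and 301 lower genes reached 2-fold. The lower bounds given for genes not above background, such as Il6, therefore hold for the main background correction only. The tested probes gave opposite calls for 18 of the 1834 genes with several of them.

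The gene lists described next had been fixed before the data were examined. Of the 26 lists with at least 5 tested genes, camera placed 12 above and 5 below the other genes. None of these 17 calls held with the correlation between genes estimated from the 4 arrays, where the smallest adjusted p was 0.142; camera then rests on 2 residual degrees of freedom.

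Cytokine genes rose nearly throughout. Of the 27 tested genes of the list of inflammatory and regulatory cytokines, 25 rose, 1 fell and 1 did not pass (adjusted over the list alone, 25 rose and 1 fell). Besides Il6 and Edn1, the largest changes were in Il23a, a cytokine subunit that pairs with the product of Il12b (at least 38.6-fold), and in the pyrogenic cytokine Tnf (5.57, SE 0.10). A dimmer second probe of Il23a rose 2.40-fold. Il1b rose with a log2 fold change of 4.13 (SE 0.09). Il12a, the subunit that completes interleukin-12, rose at least 22.1-fold and its partner Il12b at least 2.37-fold. The anti-inflammatory cytokine Il10 rose at least 8.63-fold. Vegfa, an angiogenic factor, fell (-0.51, SE 0.09; with the mean of its 2 probes -0.27, adjusted p = 0.133). Ltb did not pass (adjusted p = 0.425) and was not above background on either stimulated array. The list's median log2 fold change was 2.99 (camera adjusted p = 3.26e-15; adjusted p = 0.142 with an estimated correlation), and 1.89 without background correction.

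Among chemokines, 14 of 17 tested genes rose, 1 fell and 2 did not pass (adjusted over the list alone, 14 rose and 1 fell). Cxcl1, Cxcl2 and Cxcl10 led, followed by Ccl7, a monocyte attractant (3.89, SE 0.12), and Cxcl9, which attracts T cells, rose at least 9.62-fold. Ccl6 fell (-0.59, SE 0.09), but its value was 0.02 with scaling to the median of the tested probes. The list's median was 2.56, or 2.52 with genes below background at their bound (camera adjusted p = 2.04e-08; adjusted p = 0.142 with an estimated correlation).

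**Figure D2:**
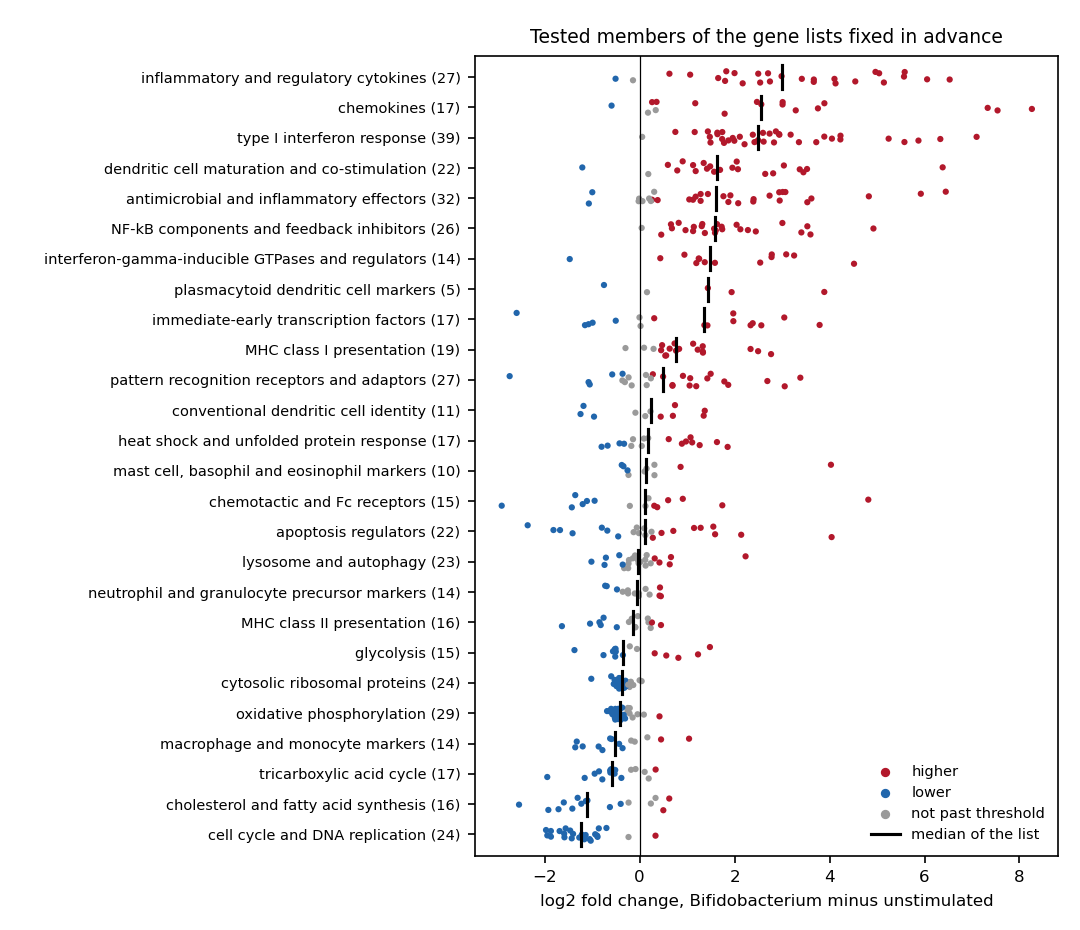
Log2 fold change (Bifidobacterium minus unstimulated, horizontal axis) of every tested gene of the 26 lists with at least 5 tested genes; each point is a gene, coloured by whether it rose, fell or did not pass an adjusted p of 0.05, and the black bar is the list's median. Numbers in parentheses are tested genes; medians run from 2.99 for cytokines to -1.25 for cell cycle genes, and that of cytosolic ribosomal proteins, -0.38 here, was 0.24 with scaling to the median of the tested probes.

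Maturation and co-stimulation genes, through which dendritic cells activate T cells, also rose. Of 22 tested genes 20 rose, 1 fell and 1 did not pass (adjusted over the list alone, 20 rose and 1 fell). Cd40 led: its 4 probes gave log2 fold changes from 2.30 to 6.38. The T cell-stimulating ligand gene Cd70 rose at least 8.54-fold, the receptor gene Slamf7 rose with 3.53 (SE 0.10), and Marcksl1, which binds actin, with 3.37 (SE 0.12). The B7 ligands Cd80 and Cd86 rose with 2.07 (SE 0.09) and 1.69 (SE 0.11). Ccr7, the receptor that guides dendritic cells to lymph nodes, rose with 1.35 (SE 0.13), the NF-kB subunit Relb with 1.12 (SE 0.21), and the adhesion molecule Icam1 with 0.59 (SE 0.10), which scaling to the median of all probes reduced to 0.13 (adjusted p = 0.506). Socs2, a feedback inhibitor of cytokine signalling, fell (-1.21, SE 0.11). Pdcd1lg2 did not pass (0.18, adjusted p = 0.184) and was at -0.58 with scaling to the median of all probes. The list's median was 1.63, or 1.59 with bounds (camera adjusted p = 3.19e-10; adjusted p = 0.215 with an estimated correlation).

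Genes of the MHC class I pathway, which presents peptides to CD8 T cells, rose while those of the class II pathway split. Of 19 tested class I genes 16 rose and 3 did not pass (adjusted over the list alone, 17 rose and 1 fell). The largest increases were in the non-classical class I gene H2-M2 (2.77, SE 0.09), in Nlrc5, which activates transcription of class I genes (2.49, SE 0.09), in the peptide transporter subunit Tap1 (2.34, SE 0.09) and in H2-M3 (1.33, SE 0.12). The 3 that did not pass were B2m (0.09, adjusted p = 0.407; 0.86 with scaling to the median of the tested probes), Calr (0.29, adjusted p = 0.0527) and Pdia3 (-0.30, adjusted p = 0.0531). The median was 0.77 (camera adjusted p = 7.12e-07; adjusted p = 0.142 with an estimated correlation), and 0.21 with scaling to the median of all probes.

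Of 16 tested class II genes 2 rose, 6 fell and 8 did not pass (adjusted over the list alone, 1 rose and 6 fell), and with scaling to the median of the tested probes 6 were higher and 5 lower. H2-DMa, which encodes a chain of the peptide-loading chaperone, fell most (-1.64, SE 0.09), followed by the lysosomal protease gene Ctsh (-1.05, SE 0.10), by H2-DMb2 (-0.85, SE 0.14) and by the protease gene Lgmn (-0.82, SE 0.09). H2-Eb1 (0.26, SE 0.09) and H2-Ob (0.45, SE 0.12) rose, but with scaling to the median of all probes were at -0.12 and -0.08, and neither call held without unstimulated replicate 1 (adjusted p = 0.0893 and 0.116) or 2 (0.144 and 0.0609). H2-Eb1 also lost its call without stimulated replicate 1 (0.0799) and 2 (0.152). H2-Ab1, a class II beta chain gene, did not pass (0.23, SE 0.09, adjusted p = 0.0614), although another of its 3 probes did (0.50, adjusted p = 0.0078). The value used for the gene passed under some alternatives, with 0.81 after scaling to the median of the tested probes (adjusted p = 4.64e-04) and 0.02 after scaling to the median of all probes. The list as a whole did not stand apart (median -0.13, camera adjusted p = 0.426), and its median ranged from -0.74 to 0.05 over the scalings.

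Type I interferon response genes rose in nearly every case. Of 39 tested genes 38 rose and 1 did not pass (adjusted over the list alone, 38 rose). Rsad2 and Oasl1 led, with Ifit2, which restrains viral translation (5.87, SE 0.09), and the nucleotide kinase gene Cmpk2 (5.58, SE 0.16). Ifnb1, the type I interferon gene itself, rose at least 7.33-fold. Ifitm1 did not pass (0.05, adjusted p = 0.64), with values of -0.41 and 0.39 under the scalings to all and to tested probes. The median was 2.49 (camera adjusted p = 6.27e-21; adjusted p = 0.2 with an estimated correlation), and 1.64 without background correction.

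Genes that interferon-gamma also induces rose too. Of 14 tested GTPases and regulators 13 rose and 1 fell (adjusted over the list alone, 13 rose and 1 fell). The guanylate-binding protein gene Gbp5 rose at least 21.7-fold, Gbp3 with 3.25 (SE 0.09), the GTPase gene Igtp with 3.09 (SE 0.09) and Gbp2 with 2.78 (SE 0.09). Ifngr1, the ligand-binding chain of the interferon-gamma receptor, fell (-1.47, SE 0.10). The median was 1.48 (camera adjusted p = 5.79e-07; adjusted p = 0.142 with an estimated correlation).

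NF-kB components and their feedback inhibitors rose together. Of 26 tested genes 25 rose and 1 did not pass (adjusted over the list alone, 25 rose). Nfkbiz, an inducible nuclear regulator of NF-kB target genes, rose with 4.92 (SE 0.10). Tnfaip3, which encodes the inhibitory enzyme A20, rose with 3.60 (SE 0.10), the adaptor gene Traf1 with 3.53 (SE 0.14) and the cytokine signalling inhibitor Socs3 with 3.41 (SE 0.09). Cyld, a deubiquitinase gene, did not pass (0.04, adjusted p = 0.7), with values of -0.51 and 0.29 under the scalings to all and to tested probes. The median was 1.59 (camera adjusted p = 5.68e-13; adjusted p = 0.142 with an estimated correlation), and 1.04 with scaling to the median of all probes.

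Pattern recognition receptors and their adaptors moved both ways. Of 27 tested genes 15 rose, 5 fell and 7 did not pass (adjusted over the list alone, 15 rose and 5 fell). Clec4e, the receptor Mincle for microbial glycolipids, rose with 3.38 (SE 0.11), the intracellular lipopolysaccharide sensor gene Casp4 with 3.05 (SE 0.10) and the co-receptor gene Cd14 with 2.69 (SE 0.09). Pycard, the inflammasome adaptor, was not above background on either stimulated array and fell at least 5.53-fold. The lipopolysaccharide receptor gene Tlr4 fell (-1.08, SE 0.11), as did the antiviral adaptor gene Mavs (-1.05, SE 0.14), the beta-glucan receptor gene Clec7a (-0.58, SE 0.12) and the peptidoglycan recognition gene Pglyrp1 (-0.36, SE 0.12). The last 2 calls were lost without an unstimulated array: Clec7a without replicate 1 (-0.54, adjusted p = 0.0581) and Pglyrp1 without replicate 2 (-0.22, adjusted p = 0.165). Pglyrp1 also lost its call without stimulated replicate 2 (-0.35, adjusted p = 0.0612). The median was 0.49 (camera adjusted p = 0.00454; adjusted p = 0.25 with an estimated correlation), from 0.27 without background correction to 1.08 with scaling to the median of the tested probes.

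Immediate-early genes, which respond to signals within minutes to hours, were also divided. Of 17 tested genes 10 rose, 5 fell and 2 did not pass (adjusted over the list alone, 10 rose and 5 fell). Rgs1, a regulator of G protein signalling, rose with 3.79 (SE 0.10), the kinase phosphatase gene Dusp4 at least 6.12-fold and the stress-response transcription factor Atf3 with 2.56 (SE 0.09). Klf4, a transcription factor of monocyte differentiation, fell at least 4.00-fold. Dimmer second probes gave a rise of 2.66-fold for Dusp4 and a fall of 2.36-fold for Klf4. Klf6 did not pass (0.02), while its dimmer second probe rose 2.04-fold. Egr2 (-1.15, SE 0.10), Klf2 (-1.08, SE 0.10), Fos (-0.99, SE 0.10) and Jun (-0.50, SE 0.10) fell as well. The median was 1.36, or 1.28 with bounds (camera adjusted p = 0.0163; adjusted p = 0.246 with an estimated correlation). The list's call was lost without stimulated replicate 1 (median 0.36) or 2 (0.23), where Dusp4, detected only after stimulation, was not tested. The call was also lost with detection on all 4 arrays (0.83, camera adjusted p = 0.0998) and with camera on ranks (adjusted p = 0.056). The median was 0.49 without background correction.

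Antimicrobial and inflammatory effector genes rose in most cases. Of 32 tested genes 24 rose, 2 fell and 6 did not pass (adjusted over the list alone, 24 rose and 2 fell). Serpinb2 and Saa3 led, with the collagenase gene Mmp13 (4.83, SE 0.09) and the cystine transporter gene Slc7a11 (3.62, SE 0.09). Nos2, the inducible nitric oxide synthase, rose at least 3.78-fold, and Ptgs2, the inducible prostaglandin synthase, at least 3.15-fold. Arg1, the arginine-degrading enzyme (-0.998, SE 0.09), and the gelatinase gene Mmp9 (-1.07, SE 0.14) fell. The median was 1.60, or 1.55 with bounds (camera adjusted p = 1.63e-10; adjusted p = 0.142 with an estimated correlation), and 1.06 without background correction.

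**Figure D3:**
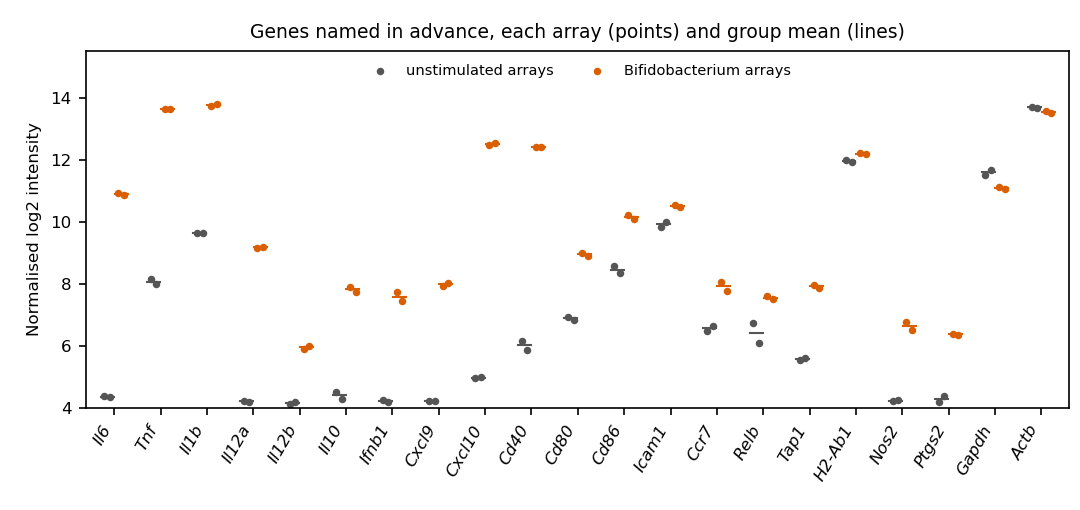
Normalised log2 intensity (vertical axis) of the 21 genes named in advance on each of the 2 unstimulated arrays (grey points) and the 2 Bifidobacterium arrays (orange points); short lines are group means. For Tnf the unstimulated mean is 8.06 and the stimulated mean 13.63; for H2-Ab1 the means are 11.96 and 12.20, and for Actb 13.69 and 13.53, a difference of -0.15 that was 0.60 with scaling to the median of the tested probes.

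Of 16 tested genes of cholesterol and fatty acid synthesis 11 fell, 2 rose and 3 did not pass (adjusted over the list alone, 11 fell and 3 rose). The fatty acid desaturase gene Scd2 fell at least 5.73-fold, the elongase gene Elovl6 at least 2.42-fold and the cholesterol reductase gene Dhcr7 at least 1.85-fold. The regulators Insig1 (0.62, SE 0.11) and Srebf2 (0.50, SE 0.09) rose, but with scaling to the median of all probes were at -0.17 and -0.26. The median was -1.12, or -0.99 with bounds (camera adjusted p = 0.0379; adjusted p = 0.414 with an estimated correlation). It was -0.60 without background correction and -1.84 with scaling to the median of all probes. The list's call was lost without unstimulated replicate 1 (median -0.86) or 2 (-0.87), where Scd2, Elovl6 and Dhcr7 were not tested. The call was also lost without stimulated replicate 1 (-0.97) and with detection on all 4 arrays (camera adjusted p = 0.116).

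Of 17 tested genes of the tricarboxylic acid cycle list 12 fell, 1 rose and 4 did not pass (adjusted over the list alone, 12 fell and 1 rose). Idh1, which fell most (-1.95, SE 0.09), encodes a cytosolic isocitrate dehydrogenase that works outside the cycle. The fumarase gene Fh1 (-1.16, SE 0.09), Idh3a (-0.95, SE 0.11) and the succinyl-CoA ligase gene Suclg1 (-0.86, SE 0.11) followed. Dlst rose (0.34, SE 0.10) but was at -0.19 with scaling to the median of all probes, and lost its call without unstimulated replicate 1 (adjusted p = 0.104), unstimulated replicate 2 (0.064) and stimulated replicate 2 (0.0888). The list's median was -0.58 (camera adjusted p = 0.0379; adjusted p = 0.25 with an estimated correlation). It was -1.04 with scaling to the median of all probes and -0.25 with scaling to that of the tested probes, where 8 genes were lower and 2 higher. Its call was lost with scaling to the median of all probes (adjusted p = 0.0769) and without stimulated replicate 1 (0.0546) or 2 (0.0575).

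Of 29 tested genes of oxidative phosphorylation 21 fell, 1 rose and 7 did not pass (adjusted over the list alone, 22 fell and 1 rose); with scaling to the median of the tested probes 4 were lower and 3 higher. The complex I gene Ndufs3 (-0.69, SE 0.12), the ATP synthase gene Atp5c1 (-0.62, SE 0.10), and Ndufb8 (-0.60, SE 0.09) and Ndufa4 (-0.57, SE 0.09) fell most, and Atp5c1 and Ndufb8 were at -0.07 and -0.04 with that scaling. Cycs, which encodes cytochrome c, rose (0.42, SE 0.14) but was at -0.07 with scaling to the median of all probes, and lost its call without unstimulated replicate 1 (adjusted p = 0.17), unstimulated replicate 2 (0.165) and stimulated replicate 1 (0.116). The list's median was -0.42, or -0.28 relative to all genes (camera adjusted p = 0.00514; adjusted p = 0.214 with an estimated correlation). The call was lost with scaling to the median of all probes (median -0.84, adjusted p = 0.522) or of the tested probes (-0.04, 0.349).

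Glycolysis genes did not stand apart as a list. Of 15 tested genes 5 rose, 8 fell and 2 did not pass (adjusted over the list alone, 5 rose and 8 fell), against 5 higher and 1 lower with scaling to the median of the tested probes. Hif1a, which activates glycolytic genes, rose with 1.48 (SE 0.10), the transporter gene Slc2a6 with 1.23 (SE 0.09), the hexokinase gene Hk3 with 0.82 (SE 0.10), the phosphofructokinase gene Pfkp with 0.56 (SE 0.10) and the glucose transporter gene Slc2a1 with 0.32 (SE 0.10), the last at -0.04 with scaling to the median of all probes. That scaling also ended the calls for Hk3 (0.19) and Pfkp (0.11). Slc2a1 lost its call without unstimulated replicate 1 (adjusted p = 0.0634), unstimulated replicate 2 (0.136) and stimulated replicate 2 (0.124). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell with -1.37 (SE 0.29). It was above background on 1 of 2 stimulated arrays and lost its call without unstimulated replicate 1. The median was -0.35 (camera adjusted p = 0.952) and ranged from -0.73 to 0.07 over the scalings. The reference gene Gapdh fell (-0.50, SE 0.10, adjusted p = 0.00548) but was at 0.07 with scaling to the median of the tested probes, and Actb did not pass (-0.15, adjusted p = 0.167) and was at 0.60 there (adjusted p = 0.00333). The 5 probes of Actb were called both ways, 1 lower (-0.42, adjusted p = 0.0101) and 1 dim probe higher (0.88, adjusted p = 0.0191).

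Cell cycle and DNA replication genes fell. Of 24 tested genes 22 fell, 1 rose and 1 did not pass (adjusted over the list alone, 22 fell and 1 rose). Cdc6, which loads the replicative helicase, had a log2 fold change of -1.97 (SE 0.15; above background on 1 of 2 stimulated arrays). The mitotic activator Cdc20 fell with -1.95 (SE 0.09), and the helicase subunits Mcm4 and Mcm6 with -1.87 each (SE 0.09 and 0.10). Tyms, which makes thymidylate, rose (0.33, SE 0.09) but was at -0.26 with scaling to the median of all probes, and lost its call without unstimulated replicate 1 (adjusted p = 0.107) and stimulated replicate 1 (0.0669). Pcna, above background on 1 of 2 stimulated arrays, did not pass (-0.24, adjusted p = 0.122), and did with scaling to the median of all probes (-0.71). The median was -1.25, or -1.22 with bounds (camera adjusted p = 2.09e-06; adjusted p = 0.142 with an estimated correlation). It was -1.11 to -1.91 over the scalings and -0.68 without background correction.

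Cytosolic ribosomal protein genes had no direction that held across scalings. Of 24 tested genes 17 fell and 7 did not pass (adjusted over the list alone, 19 fell), but with scaling to the median of the tested probes 8 were higher and 1 lower. Rpl22 fell with -1.02 (SE 0.09). Rpl35 (-0.60, SE 0.11) and Rps19 (-0.53, SE 0.09) fell too, but were at 0.08 and 0.17 with that scaling. The median was -0.38 (camera adjusted p = 0.00701; adjusted p = 0.25 with an estimated correlation), and 0.24 with that scaling. The call was also lost with cyclic loess (adjusted p = 0.133), with scaling to the median of all probes (0.894) or of the tested probes (0.199) and without stimulated replicate 2 (0.059).

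Markers of cell types that GM-CSF cultures can hold moved in different directions. Of 11 tested genes of conventional dendritic cell identity 5 rose, 3 fell and 3 did not pass (adjusted over the list alone, 5 rose and 3 fell). The transcription factor genes Irf8 (1.37, SE 0.10) and Id2 (0.74, SE 0.11) and the migration receptor gene Ccr7 rose, as did the integrin gene Itgax (0.70, SE 0.09) and Zbtb46 (0.44, SE 0.13). Zbtb46 was at -0.17 with scaling to the median of all probes, and lost its call without unstimulated replicate 2 (adjusted p = 0.142) and stimulated replicate 2 (0.0564); Id2 and Itgax lost theirs with that scaling (0.18 and 0.04). Batf3 (-1.25, SE 0.13), a transcription factor of cross-presenting dendritic cells, and the lectin genes Mgl2 (-1.18, SE 0.09) and Clec10a (-0.96, SE 0.12) fell. Sirpa did not pass (-0.09), while its dimmer second probe rose with 1.25. The list did not stand apart (median 0.23, camera adjusted p = 0.283), and its median was -0.32 with scaling to the median of all probes.

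Of 14 tested macrophage and monocyte markers 9 fell, 2 rose and 3 did not pass (adjusted over the list alone, 9 fell and 2 rose). The high-affinity Fc receptor gene Fcgr1 (-1.36, SE 0.10), the mannose receptor gene Mrc1 (-1.33, SE 0.10) and the M-CSF receptor gene Csf1r (-1.20, SE 0.10) fell. Adgre1, an adhesion receptor gene used to mark mouse macrophages, rose (1.04, SE 0.09), and so did Ly6c1 (0.45, SE 0.10). Both lost their calls with scaling to the median of all probes (adjusted p = 0.0575 and 0.746), and Ly6c1 also without unstimulated replicate 1 (0.0556). The list did not pass (median -0.51, camera adjusted p = 0.15), and its median ranged from -0.87 with scaling to the median of all probes to -0.07 with scaling to that of the tested probes, where 6 markers were lower and 3 higher.

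Of 14 tested neutrophil and granulocyte precursor markers 3 rose, 3 fell and 8 did not pass (adjusted over the list alone, 2 rose and 3 fell). Ltf (-0.73, SE 0.10), Cebpe (-0.69, SE 0.09) and S100a9 (-0.48, SE 0.09) fell, and S100a9 was at 0.05 with scaling to the median of the tested probes. The granule protein genes Camp (0.43, SE 0.09), Ctsg (0.42, SE 0.09) and Mpo (0.45, SE 0.16) rose but were at -0.37, -0.28 and -0.28 with scaling to the median of all probes. Mpo lost its call without unstimulated replicate 1 (adjusted p = 0.213), unstimulated replicate 2 (0.136) and stimulated replicate 1 (0.138). The median was -0.06 (camera adjusted p = 0.956), and ranged from -0.56 to 0.23 over the scalings.

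Of 10 tested mast cell, basophil and eosinophil markers 2 rose, 3 fell and 5 did not pass (adjusted over the list alone, 2 rose and 2 fell). Hdc, the enzyme that makes histamine, rose from 6.87 ± 0.10 to 10.90 ± 0.01 log2 units (mean ± SD, n = 2 each; log2 fold change 4.03, SE 0.10). Il4 rose with 0.86 (SE 0.23), losing its call without unstimulated replicate 1 (adjusted p = 0.12) and 2 (0.106). The eosinophil granule genes Ear2 (-0.38, SE 0.09) and Prg2 (-0.34, SE 0.09) and the IgE receptor gene Fcer1a (-0.26, SE 0.09; above background on 1 of 2 stimulated arrays) fell, but were at 0.27, 0.25 and 0.04 with scaling to the median of the tested probes. Without unstimulated replicate 1 the adjusted p-values were 0.0573 for Ear2, 0.0797 for Prg2 and 0.148 for Fcer1a, and Fcer1a also lost its call without unstimulated replicate 2 (0.15) and stimulated replicate 2 (0.139). The median was 0.12 (camera adjusted p = 0.426), with -0.47 to 0.32 over the scalings.

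Of 5 tested plasmacytoid dendritic cell markers 3 rose, 1 fell and 1 did not pass (adjusted over the list alone, 3 rose and 1 fell). Irf7 (3.89, SE 0.10; above background on 1 of 2 unstimulated arrays) and Bst2 (1.44, SE 0.10) are also in the type I interferon list, and the transcription factor gene Tcf4 rose with 1.94 (SE 0.10). Pacsin1 fell (-0.75, SE 0.20; above background on 1 of 2 stimulated arrays), losing its call without unstimulated replicate 1 (-0.52, adjusted p = 0.117), and Cox6a2, also above background on 1 of 2 stimulated arrays, did not pass (0.15, adjusted p = 0.469). The median was 1.44 (camera adjusted p = 0.0379; adjusted p = 0.345 with an estimated correlation), and 0.93 with scaling to the median of all probes. The list's call was lost without unstimulated replicate 2 (adjusted p = 0.0881), without stimulated replicate 1 (0.0554), with scaling to the median of the tested probes (0.0632) and with camera on ranks (0.056).

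Markers of lymphoid, erythroid and stromal cells had too few tested genes for a list test, since most members on the array were not above background. Of 16 T and NK cell markers on the array 4 were tested, and these rose (4 adjusted over the list alone): Il7r (1.36, SE 0.09), Lck (at least 1.36-fold), Thy1 (0.50, SE 0.12) and Prf1 (0.49, SE 0.16). Thy1 and Prf1 were at -0.000597 and -0.28 with scaling to the median of all probes. Without unstimulated replicate 1 or 2 the adjusted p-values were 0.0643 and 0.0841 for Thy1 and 0.115 and 0.171 for Prf1, which also lost its call without stimulated replicate 1 (0.081). Of 12 B cell markers on the array 2 were tested and rose (2 adjusted over the list alone), Blnk with 1.54 (SE 0.12) and Fcmr at least 1.32-fold. Of 2 tested erythroid markers (14 on the array) Car2 rose (1.38, SE 0.10) and Tfrc did not pass (-0.18, adjusted p = 0.197), and did with scaling to the median of all probes (-0.93). Of 3 tested stromal and endothelial markers (15 on the array) Vcam1 (2.79, SE 0.13) and Thy1 rose, and Acta2 did not pass (0.20, adjusted p = 0.093) and was at -0.57 with scaling to the median of all probes. Adjusted over each list alone, 1 erythroid and 2 stromal genes rose.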

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

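The counts of changed genes rest on choices that 4 arrays cannot settle. Without background correction 382 higher and 301 lower genes reached 2-fold, and with normexp without negative controls 461 and 405. Scaling to the median of all probes gave 744 higher and 5266 lower genes, of which 358 and 2433 reached 2-fold, and 130 calls turned to the opposite direction. Scaling to the median of the tested probes, added after the data were seen, gave 2709 and 2044, with 43 opposite. Without variance moderation 1160 and 1604 genes passed, and treat against a 2-fold change gave 440 higher and 338 lower. Leaving out 1 array gave 1535 to 1772 higher and 1852 to 2929 lower genes; without unstimulated replicate 1 the lower genes were 1852, and without unstimulated replicate 2 they were 1948. No main call turned to the opposite direction when an array was left out. Such fits have 1 residual degree of freedom and take the spread from the other group alone, so a call lost in them does not by itself show a smaller change. They also tested fewer genes: 6846 and 6836 without unstimulated replicate 1 and 2, and 7350 and 7395 without stimulated replicate 1 and 2, against 7557. Part of the lower counts is therefore genes that were not tested. Lists called lower numbered 5, against 2 with scaling to the median of all probes, 3 with scaling to the median of the tested probes, and 3 each without stimulated replicate 1 and without stimulated replicate 2. With an estimated correlation 0 lists were called higher and 0 lower (smallest adjusted p 0.142 with camera, where fry called 16 higher and 7 lower). Camera on ranks, also added after the data were seen, gave 9 higher and 5 lower lists. As a self-contained test, fry put the glycolysis list higher (adjusted p = 0.00289) although its median was -0.35, while camera had no call for it (adjusted p = 0.39 to 0.962 over 7 scalings and background corrections). With the replicate block 1920 genes were higher and 2925 lower (718 and 797 by at least 2-fold), 12 lists higher and 5 lower; the samples share only a number, and the correlation of their deviations was -0.0086. A slide block was not run because the files give no slide. The array names in the sample titles number the groups far apart, so slide or processing batch may coincide with stimulation. If so, they cannot be told apart from it.

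With scaling to the median of all probes, these values had the opposite sign: Mpo -0.28, Thy1 -0.000597, Prf1 -0.28, Ifitm1 -0.41, Tyms -0.26, Cycs -0.0739, Dlst -0.19, Insig1 -0.17, Srebf2 -0.26, H2-Eb1 -0.12, H2-Ob -0.0781, Zbtb46 -0.17, Ctsg -0.28, Camp -0.37, Mcoln1 -0.19, Npc2 -0.21, Slc2a1 -0.0412, Pdcd1lg2 -0.58, Cyld -0.51 and Acta2 -0.57. The ribosomal list kept a negative median there (-0.55) but lay above the median of all genes. With scaling to the median of the tested probes the opposite sign was found for Rpl35 0.0825, Rps19 0.17, S100a9 0.0498, Fcer1a 0.0422, Prg2 0.25, Ear2 0.27, Gapdh 0.0657, Actb 0.60, Ccl6 0.0241, Lamp1 0.16, Ltb 0.49 and the ribosomal list (0.24). For these and the other results that did not hold, the cause was not tested.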

Other observations

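Of the 6 tests described here, 4 were chosen only after the result was seen. Those of probe base composition and of dim probes were set before, except for the values of the dim probe test with other scalings. Regulators of apoptosis changed in both directions: of 22 tested genes 9 rose, 7 fell and 6 did not pass (adjusted over the list alone, 9 rose and 7 fell). The stress-induced genes Gadd45b (4.04, SE 0.14) and Gadd45a (2.14, SE 0.13) rose, while Gadd45g (-2.36, SE 0.11) and the executioner caspase gene Casp6 (-1.82, SE 0.19) fell. The list did not stand apart (median 0.11, camera adjusted p = 0.283), and its median was -0.48 with scaling to the median of all probes (6 higher, 13 lower) and 0.31 with scaling to that of the tested probes (12 higher, 7 lower). Of 15 tested chemotactic and Fc receptors 6 rose, 6 fell and 3 did not pass (adjusted over the list alone, 6 rose and 6 fell). Ccrl2, which binds the chemoattractant chemerin, rose with 4.82 (SE 0.12) and the formyl peptide receptor gene Fpr1 with 1.74 (SE 0.11). The nucleotide receptor gene P2ry6 fell with -2.91 (SE 0.10), and the chemokine receptor gene Cxcr4 with -1.43 (SE 0.10; above background on 1 of 2 stimulated arrays). This list did not stand apart either (median 0.12, camera adjusted p = 0.801), with -0.43 to 0.37 over the scalings.

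Of 17 tested heat shock and unfolded protein response genes 8 rose, 4 fell and 5 did not pass (adjusted over the list alone, 8 rose and 4 fell). The inducible chaperone gene Hspa1a rose at least 2.81-fold, Chac1, which degrades glutathione, with 1.63 (SE 0.10), the asparagine synthetase gene Asns with 1.26 (SE 0.09) and the endoplasmic reticulum chaperone gene Hspa5 with 1.11 (SE 0.12). Xbp1 (-0.80, SE 0.09), Hspa8 (-0.68, SE 0.09), Hspd1 (-0.42, SE 0.12) and Dnajb1 (-0.33, SE 0.11) fell, and all 4 lost their calls with scaling to the median of the tested probes. Hspd1 also did so without unstimulated replicate 1 (adjusted p = 0.089), and Dnajb1 without unstimulated replicate 1 (0.13), unstimulated replicate 2 (0.115) and stimulated replicate 1 (0.136). Together they had a median of 0.18 (camera adjusted p = 0.0457; adjusted p = 0.25 with an estimated correlation). Its call was lost without unstimulated replicate 1 (adjusted p = 0.116), unstimulated replicate 2 (0.104), stimulated replicate 1 (0.0586) and stimulated replicate 2 (0.0645). It was also lost without background correction (0.0762), with normexp without negative controls (0.0626), with scaling to the median of all probes (median -0.02, 0.0586), with detection on all 4 arrays (0.149) and with camera on ranks (0.056).

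Of 23 tested lysosome and autophagy genes 5 rose, 5 fell and 13 did not pass (adjusted over the list alone, 4 rose and 5 fell). The autophagy receptor gene Sqstm1 rose with 2.23 (SE 0.10). Gabarapl1 (0.63, SE 0.09), Atp6v1h (0.66, SE 0.10), Mcoln1 (0.42, SE 0.15) and Npc2 (0.32, SE 0.09) rose but lost their calls with scaling to the median of all probes, where Mcoln1 and Npc2 were at -0.19 and -0.21. The glucuronidase gene Gusb fell with -1.02 (SE 0.10), and so did the proton pump gene Atp6v1b2 (-0.74, SE 0.09), Grn (-0.71, SE 0.09) and Lamp1 (-0.43, SE 0.10). Of these, Atp6v1b2, Grn and Lamp1 lost their calls with scaling to the median of the tested probes, where Lamp1 was at 0.16. Without unstimulated replicate 1 or 2 the adjusted p-values were 0.124 and 0.209 for Mcoln1, 0.0772 and 0.0719 for Npc2, and 0.0701 and 0.0531 for Lamp1. Without stimulated replicate 2 that of Mcoln1 was 0.142, and without stimulated replicate 1 that of Npc2 was 0.0645. As a list these genes had a median of -0.03 (camera adjusted p = 0.801), with -0.59 to 0.20 over the scalings.

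More genes were lower than higher with quantile normalisation, with a ratio of 1.53. Ratios with an array left out are not used here, since the filter then removes genes detected only in the group left with 1 array. The ratio was 1.11 with cyclic loess, 0.755 with scaling to the median of the tested probes and 7.08 with scaling to the median of all probes; each scaling sets this balance by how it centres the genes, so an effect of the quantile step cannot be told apart from a change in the cells. Base composition of the probes cannot be told apart as a cause either. Over 3 equal groups by probe GC the ratios were 1.199 (95% lower bound 1.09), 1.66 and 1.83. The correlation of fold change with GC was -0.062 (Spearman). Loss of dim probes in the background cannot be told apart from the other causes. Among the brightest of 3 equal groups of genes the ratio was 1.64, but centring sets it too. It was 0.99 with cyclic loess, 0.624 with scaling to the median of the tested probes and 5.58 with scaling to that of all probes. Of the lower genes 513 were not above background on either stimulated array, and of the higher genes 142 on either unstimulated array. Changes in the cells could give such counts too. Whether Bifidobacterium lowers more genes than it raises stays open.

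Cell cycle genes were lower on the stimulated arrays. Scaling does not account for this, as the list's own median was -1.11 at its highest over 4 scalings (SD of its members 0.54); it was -0.68 without background correction. Fewer granulocyte precursors, which divide in such cultures, would lower their markers too. The neutrophil and granulocyte precursor list had a median of -0.0594 (SD of its members 0.39), against -1.25 for the cell cycle list. That list mixes precursor with neutrophil markers, and its members were divided (3 rose, 3 fell and 8 did not pass, with Cebpe at -0.69 and Mpo at 0.45). Its median ranged from -0.56 to 0.23 over the scalings, so it cannot exclude a loss of precursors. Macrophage and monocyte markers were divided (9 of 14 lower and 2 higher, among them Fcgr1 with -1.36 and Adgre1 with 1.04; 6 lower and 3 higher with scaling to the median of the tested probes), so loss of dividing cells of that lineage stays open. An exit from the cycle within 4 hours of contact may be another cause, and counts of dividing cells per cell type would tell these apart.

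Hdc rose with a log2 fold change of 4.03. More mast cells or basophils would raise their other markers too. The other members of the mast cell, basophil and eosinophil list had a median of 0.10 (SD 0.41). This argues against that cause for a rise of the size seen in Hdc. Il4 rose (0.86). Fcer1a and the eosinophil genes Ear2 and Prg2 were lower, but were at 0.04, 0.27 and 0.25 with scaling to the median of the tested probes. Induction of Hdc within the dendritic cells or another myeloid cell may be the cause, and the arrays do not say which cell makes it. Staining for the enzyme together with cell markers would.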
